A study of Homo sapiens with 12 samples.

How the data were processed

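Total RNA from 12 samples was measured on Illumina HT-12 v4 BeadChips, whose probes are oligonucleotides on beads, each probe being read from many beads per array. The samples were 3 human B-cell lines that received 2 µg of an expression plasmid by nucleofection, an electrical way of bringing DNA into cells. Each line received either the KLF4 plasmid or the empty vector, and RNA was taken at 3 h and at 10 h. JeKo-1 came from a mantle cell lymphoma, and MEC1 and MEC2 are sister lines from a chronic B-cell leukemia. The groups were empty vector at 3 h, KLF4 at 3 h, empty vector at 10 h and KLF4 at 10 h, each with 1 array per line, so that n = 3 lines. All 12 arrays were on 1 chip. The labels do not say whether the arrays of a line came from separate cultures, so every p-value measures only the spread between these samples. The JeKo-1 cells were grown in another medium and serum concentration than the MEC cells, so line and medium cannot be told apart in any comparison of JeKo-1 with the MEC lines.

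Per the file headers, the first deposited table holds for each probe and array a mean, read here as an intensity, and a p-value. The means are not background-subtracted and not normalized between arrays. The p-values fall with rising intensity and become too small to be ranks among negative control probes, and the method behind them is not given in the sources used here. The authors also deposited a table of normalized intensity on a linear scale. Its column medians ran from 99.43 to 102.2, its values were neither centred nor log-transformed, and they followed a quantile normalization of the means in the first table, with a log2 standard deviation of at most 0.0272. The software behind both tables is not given in the sources used here.

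The comparisons started from the unnormalized means and used limma 3.58.1 in R 4.3.3. The table held 47323 probes, of which 4 had an empty cell and were left out. The background was estimated from the probes' detection p-values and removed with limma's normexp model with an offset of 16, and the 47319 probes were put on the log2 scale and quantile-normalized. The estimate takes these p-values as ranks among negative control probes, which they are too small to be. Its error is therefore not known, and leaving out the background step changed several counts, as given below. A probe was tested when its detection p was under 0.01 on at least 3 of the 12 arrays, which left 21141 probes. Of these, 16015 carried the name of 1 gene, 4 carried several names and 5122 carried none. The named probes stood for 11943 genes, of which 3206 had more than 1 detected probe, and 16009 of the named probes were found in the gene table by their gene number. A gene was represented by its detected probe with the highest mean over the 12 arrays. Between 16924 and 19205 probes were detected per array, and the 95th percentile of intensity was 13.1 to 17.9 times the mean background. The number of arrays limits the precision.

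The plasmid effect was fitted with each line and time as a pair of arrays, at 3 h, at 10 h, over both times, as the difference between the times, and as the difference between the MEC lines and JeKo-1. The deviations of the arrays of a pair from their group means correlated between 0.79 and 0.90 across probes, so the pairing removed differences between lines. The change from 3 h to 10 h without KLF4 was fitted with the line as a term, and the line comparisons with the group as a term. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over the 21141 probes in limma's moderated test, with the spread shared by all arrays in a fit. These 8 comparisons, the lists below, the filters and the rule for naming genes were chosen before the data were examined. Fits of the MEC1 and MEC2 arrays alone, at 3 h and at 10 h, were added after the data had been seen and have 2 residual degrees of freedom.

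KLF4 was read first, by each of its probes on each array. Each comparison then names the 12 genes with the largest rise and the 12 with the largest fall among those that passed and moved alike in every pair or line, or 8 in each direction between lines. Where fewer than 6 passed in a direction, the genes with the smallest p are named up to 6 and said not to have passed. A few genes that the rule names are not reported here. Up to 4 members of each list with the smallest p serve as examples. Where a probe was detected on no array of a group, a fold is a lower bound, taken against the lowest detected signal of each array or the probe's own signal if that was higher.

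The 21 lists covered CDK inhibitors and growth arrest, cell-cycle progression, pro-apoptotic genes, anti-apoptotic genes, p53 targets, the NOTCH pathway, the KLF and SP family, epithelial differentiation, pluripotency, JNK pathway kinases, immediate-early genes, interferon-stimulated genes, NF-kB and cytokine genes, heat shock, unfolded protein and amino acid stress, B-cell identity and the B-cell receptor, markers of chronic lymphocytic leukemia and mantle cell lymphoma, glycolysis and hypoxia, cholesterol synthesis, ribosome biogenesis, and housekeeping. Another 5 lists held markers of T cells, NK cells, myeloid cells, erythroid cells and fibroblasts. Each list with at least 3 measured members was tested with camera, which compares its genes with all other genes, at a preset correlation of 0.01 and at an estimated one. It was also tested with fry, which asks whether its genes moved on balance one way. Both were adjusted over the lists of a comparison. List members that were not measured were not used here.

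The steps were tested on simulated data with 200 changed probes among 21141. Of the probes changed by 1 log2 unit, 74% were found for KLF4 at 3 h, 77% at 10 h, 95% over both times, 29% for the difference between the times, 19% for the difference between the MEC lines and JeKo-1, 54% for time, 86% for the MEC lines against JeKo-1 and 77% for MEC2 against MEC1. In the MEC lines alone, 19% were found at 3 h and 48% at 10 h. At 2 log2 units the share was at least 96% in every comparison. Each simulated change followed the fitted design, so for KLF4 at 10 h it was equal in all 3 lines. The shares do not cover changes whose size differs between lines. A count of 0 in the data therefore does not show that changes of 2 log2 units were absent. In a simulated camera test for KLF4 at 10 h with 20 lists of 20 genes, the list shifted by 0.5 was called and 0 others were. The simulated noise was independent between genes. This run therefore does not show how often camera at the preset correlation calls an unchanged list whose genes vary together.

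The alternatives were no background subtraction, an offset of 50, median scaling, the deposited normalized values, no filter, detection on 6 arrays, an intensity trend with robust variance, chip position as a covariate, other pairings, subsets of the arrays, all detected probes of a gene, and leaving out each line. For the counts of probes, other splits of the same arrays were also fitted.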

Results

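The 12 arrays measured gene expression in JeKo-1, MEC1 and MEC2 cells 3 h and 10 h after nucleofection with a KLF4 plasmid or the empty vector. Each of the 4 groups held 3 arrays, 1 per line. The 95th percentile of intensity per array lay between 1189 and 1780, and array pairs of 1 line and time correlated between 0.979 and 0.989 across probes. The comparisons ask which genes differ when a B-cell line carries the plasmid for KLF4, a zinc finger transcription factor that can switch genes on or off and restrains division in several cell types.

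The chip carried 2 probes for KLF4, and neither rose in the arrays labelled KLF4. At 3 h the first probe differed by -0.28 ± 0.17 (log2, SE, n = 3 pairs, limma adjusted p = 0.9501) and the second by 0.15 ± 0.14 (adjusted p = 0.9601). At 10 h they differed by -0.40 ± 0.17 (adjusted p = 0.7888) and -0.15 ± 0.14 (adjusted p = 0.9129). In JeKo-1 both probes stayed below detection on all 4 arrays, from 4.16 to 4.59. In MEC2 the first probe lay between 5.90 and 6.35 on all 4 arrays. Where the probes bind along the transcript was not used here, and a plasmid insert may lack that stretch. The arrays are therefore named by their labels, and the amount of KLF4 in the cells is not given by these probes.

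**Figure D1:**
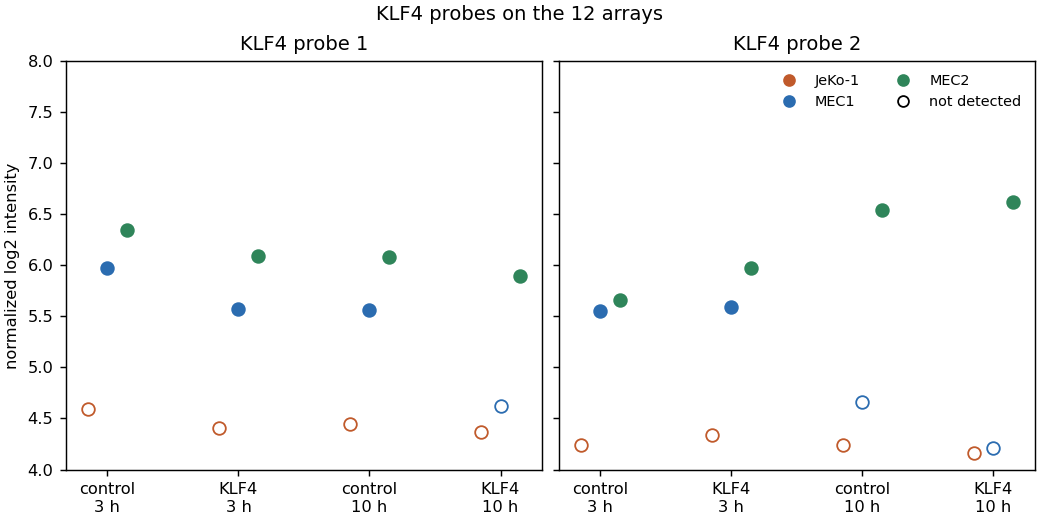
Normalized log2 intensity of both KLF4 probes on each array, by group on the horizontal axis and by line in colour, with open circles for signals that were not detected. The first probe is lower in the KLF4 array than in its control in each of the 6 pairs.

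At 3 h the plasmid comparison asks which genes respond first. The smallest p-value among higher genes belonged to FOSL1, an AP-1 subunit, at 0.79 ± 0.12 (log2, SE, n = 3 pairs). CXCL8, the neutrophil-attracting chemokine, was lower by -0.96 ± 0.18. HES5, a repressor switched on by NOTCH, was higher by 0.97, while the growth-signal genes EGR1, FOS and EGR3 differed by -0.51, -0.55 and -0.50. The hypoxia gene NDRG1 differed by 0.98 and the chaperone HSPA1A by 0.61. The others named by their p were NUDCD1 (0.73), PRSS2, C7orf57, CCR8 and MFAP3 among higher genes and ESF1 (-0.68), ZNF385B, HUS1 and MIR3142HG among lower ones. None of these genes passed. Limma called 0 of the 21141 probes, with a smallest adjusted p of 0.8159. At unadjusted p under 0.05 there were 1198 probes, 585 higher and 613 lower, where chance gives 1057. In 24.6% of probes all 3 pairs moved alike, against 25.00% by chance. No list passed: the smallest camera adjusted p was 0.06818, shared by NF-kB and cytokine genes (median -0.15), immediate-early genes (median -0.10) and the NOTCH pathway (median 0.27). Adjusted over the list alone, 1 immediate-early gene was higher and 3 were lower, and 1 NF-kB and cytokine gene was lower, beside 0 over all probes. Without JeKo-1, 3 probes passed.

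At 10 h the comparison asks which genes differ once the plasmid has had time to act. The higher genes with the smallest p encode a calcium-dependent membrane protein that limits inflammation, ANXA1 at 2.28 ± 0.32 (fold 4.86), and a glutamate receptor subunit of neurons, GRIN1 at 4.37 ± 0.64. With them came CARD19, a partner of the NF-kB adaptor BCL10, at 1.28 ± 0.16, CPLX1, which times vesicle release, at 1.13 ± 0.15, and the potassium channel KCNH3 at 0.81. Among cell-cycle brakes, CDKN2D, CDKN2B and CDKN1A, inhibitors of cyclin-dependent kinases, were higher by 1.15 ± 0.20, 1.08 ± 0.36 and 0.80 ± 0.23. CDKN2B differed by only 0.13 in JeKo-1, against 1.26 in MEC1 and 1.85 in MEC2. In the same order CDKN1A differed by 0.08, 0.92 and 1.40, and CDKN2D by 0.73, 1.04 and 1.68. The growth-arrest gene BTG1 was lower in all 3 lines, by -0.45 ± 0.12. The NOTCH genes HES4 (2.27), HES5 (1.23) and NOTCH1 (1.05) were higher, as were KLF9 (1.29), a relative of KLF4, and SPIB (1.58), a B-cell transcription factor. The lower genes were NADK2 (-0.75), which makes mitochondrial NADP, the repressor subunit SINHCAF (-0.68), the chloride transporter CLCN5 (-0.70), SSC5D, GGTLC1 and NFIC.

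None of these genes passed at 10 h. Limma called 0 of the 21141 probes, with a smallest adjusted p of 0.2891, while 1860 probes had an unadjusted p under 0.05, 1011 of them higher. All 3 pairs moved alike in 30.8% of probes, against 25.00% by chance. Across probes, which are not independent replicates, the MEC1 and MEC2 pairs correlated at 0.36 (Pearson) and 0.12 (Spearman), JeKo-1 and MEC2 at 0.20 by both measures, and JeKo-1 and MEC1 at 0.05 and 0.01. Without JeKo-1 54 probes passed. The count also changed with the processing, to 46 probes when no background was subtracted, 55 on the deposited normalized values, 36 with an intensity trend and 4 with an offset of 50.

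Among the lists at 10 h, the interferon-stimulated genes, which cells switch on against viruses and foreign nucleic acid, were higher: the median was 0.38, and 19 of 21 members were positive (camera adjusted p = 2.76e-07, adjusted p = 0.6807 with an estimated correlation). The antiviral regulators IRF7 (0.79), RIGI (0.64) and OAS1 (0.60) made up the count of 3 adjusted over the list alone, beside 0 over all probes. IRF7 was higher by 0.58 in JeKo-1, 1.16 in MEC1 and 0.65 in MEC2. In the same order OAS1 was higher by 0.49, 1.03 and 0.29, and RIGI by 0.84, 0.34 and 0.75. These genes were thus higher in every line, while the call of the whole list came mostly from JeKo-1. Its pair at 10 h had a median of 0.97 with 21 of 21 members higher, against 0.11 in MEC1 and 0.18 in MEC2, and without JeKo-1 the median was 0.06 (adjusted p = 0.1178). Without MEC1 it was 0.59. Ribosome biogenesis genes, which build the cell's protein factories, were lower, with a median of -0.21 and 1 of 11 members positive (adjusted p = 0.002306, adjusted p = 0.3947 with an estimated correlation, fry adjusted p = 0.006793). The nucleolar proteins RRP9, NOP58 and NCL differed by -0.49, -0.40 and -0.30, and without JeKo-1 the median stayed at -0.22 while the adjusted p was 0.0759. The NK cell markers, genes of the cytotoxic granule, were higher with a median of 0.83 over 3 members (adjusted p = 0.002306, adjusted p = 0.4412 with an estimated correlation): PRF1 by 1.41, NKG7 by 0.83 and GNLY by 0.44, and 3 passed adjusted over the list alone. The median was 0.46 without MEC1, 0.47 without MEC2 and 0.47 without background subtraction. PRF1 was carried by MEC2, at 3.28 against 0.62 in MEC1 and 0.31 in JeKo-1.

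**Figure D2:**
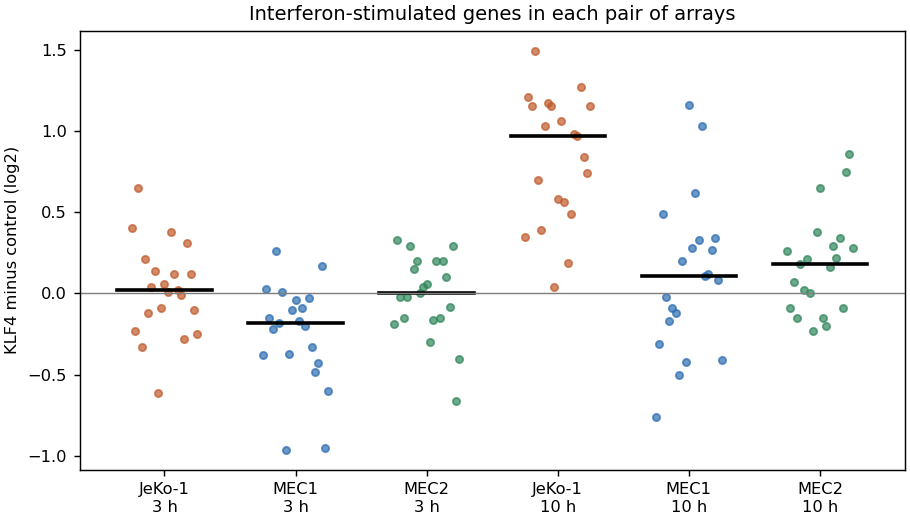
Log2 difference between the KLF4 array and its control for each of the 21 interferon-stimulated genes (points) in each pair of line and time, with the median as a black bar. The JeKo-1 pair at 10 h has a median of 0.97, and the other pairs lie between -0.18 and 0.18.

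No other list passed at 10 h. The camera adjusted p was 0.06027 for NF-kB and cytokine genes (median -0.10), 0.4728 for the NOTCH pathway (median 0.04), heat shock (0.06) and epithelial differentiation (0.09), and 0.54 for CDK inhibitors and growth arrest (0.03). It was 0.8991 for immediate-early genes (-0.08), anti-apoptotic genes (-0.08), the KLF and SP family (-0.06), the leukemia and lymphoma markers (0.09), JNK kinases (-0.13) and p53 targets (-0.03). It was 0.9311 for cholesterol synthesis (-0.05), B-cell identity (-0.02) and myeloid markers (0.12), 0.98 for pro-apoptotic genes (-0.01), and 0.9915 for glycolysis and hypoxia (-0.10), housekeeping (0.02), cell-cycle progression (-0.01) and unfolded protein and amino acid stress (-0.00). Adjusted over the list alone, 3 NOTCH genes were higher, 2 genes of the CDK inhibitor list were higher and 1 lower, in the KLF and SP family 3 were higher and 1 lower, and in B-cell identity 1 was higher and 2 were lower, beside 0 over all probes. Several medians near 0 differed in sign from the mean and the test: the KLF and SP family, p53 targets, cholesterol synthesis and B-cell identity had negative medians and positive means. The same held for glycolysis and hypoxia and for pro-apoptotic genes, while the leukemia and lymphoma markers and housekeeping had a positive median and a negative mean, and cell-cycle progression a negative median and a positive test. In 4 lists too few genes were detected for a test: DNMT3B differed by 0.38 and TERT by -0.01 for pluripotency, the T cell marker CD2 by -0.10, the erythroid marker HBA1 by 4.98 and the fibroblast gene COL1A1 by 0.85.

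In the MEC lines alone the largest rises were those of globin genes. HBA2 and HBA1, which carry oxygen in red cells, rose at 3 h by 5.43 ± 0.27 (n = 2 lines, limma adjusted p = 0.02883, at least 41.8-fold) and 4.02 ± 0.22 (adjusted p = 0.03787, at least 15.8-fold). At 10 h they had risen by 7.97 ± 0.27 and 7.07 ± 0.22 (at least 120-fold), both with an adjusted p of 0.002474. The HBA2 probe was detected on 1 of the 2 control arrays at 10 h, so its difference is measured against a signal near background. HBZ, the embryonic globin of the same cluster, rose by 4.52 ± 0.42 (adjusted p = 0.03659, at least 20.4-fold). The probes of HBA1 and HBA2, and those of LGALS7 and LGALS7B, read near-identical transcripts, so the copy that rose is uncertain.

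Among genes that passed in the MEC lines at 10 h, GRIN1 (5.27) rose most apart from the globins. KISS1R (4.86), the receptor of a metastasis-suppressing peptide, LGALS7B (4.80), a galectin of stratified skin, and CLIC3 (4.71), a chloride channel protein, came next. Then came IGFBP6 (4.52), which binds insulin-like growth factor, CKM (4.16), the creatine kinase of muscle, and NIBAN2 (4.07). NSG1 (3.67), a neuronal endosome protein, and TUBB3 (3.65), the tubulin of neurons, followed. Regulators rose too: HES4 by 2.95 ± 0.23 (adjusted p = 0.02803), KLF9 by 1.82 ± 0.16 (adjusted p = 0.03445), the imprinted RNA H19 by 3.27 (at least 8.95-fold), the growth factor MDK by 2.35, the phosphatase PTP4A3 by 2.99 and S100A11 by 1.93. HES5 (1.60), SPIB (2.02), NOTCH1 (1.34), CDKN2B (1.55 ± 0.24), CDKN2D (1.36) and CDKN1A (1.16) were higher and did not pass, with CDKN2B, CDKN2D and CDKN1A passing adjusted over the list alone. The lower genes with the smallest p were ARMC9, POU2F3, TMEM132A, CALHM5, CCDC9 and MCRIP1, and none passed.

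Of 21141 probes, limma called 54 in the MEC lines at 10 h, all higher, for 37 genes, and 3 at 3 h, all higher, for 2 genes. At unadjusted p under 0.05 there were 1765 probes at 10 h (1055 higher) and 1342 at 3 h (772 higher). Of the 37 genes, 14 were detected on no MEC control array at 10 h and 16 on both, and all 37 on both KLF4 arrays. Their median difference was 2.58 in MEC1 and 3.24 in MEC2 at 10 h, 0.69 and 0.75 at 3 h, and 0.40 in JeKo-1 at 10 h, where 34 of 37 were higher. The test of the difference between the MEC lines and JeKo-1, over both times, passed for no probe (smallest adjusted p = 0.7514). That test takes the 3 h and 10 h pairs of a line as replicates, so an effect that grows with time widens its spread. At 3 h the genes with the smallest p that did not pass were CYSRT1, TUBB3 (2.15), HES5 (1.51) and IGFBP6 (3.13) among higher ones and HCAR2, SGSH, CXCL8 (-1.17), HCAR1 and HUS1B among lower ones. The NOTCH pathway list was higher at 3 h, with a median of 0.34 (camera adjusted p = 0.00416, adjusted p = 0.8231 with an estimated correlation), and 2 members, HES5 and HES4, passed adjusted over the list alone, beside 0 over all probes. Under median scaling this list's adjusted p was 0.0662, and without background subtraction its median was 0.20. At 10 h the NK cell markers were higher, with a median of 1.15 (adjusted p = 0.01134, adjusted p = 0.6711 with an estimated correlation), or 0.64 without background subtraction. The median of these 3 genes was 0.62 in MEC1 and 0.63 in MEC2, since the 1.15 is the mean of NKG7, at 1.66 and 0.63. At 3 h, HBA2 and HBA1 did not pass with chip position as a covariate (5.16, adjusted p = 0.07311, and 3.79, adjusted p = 0.1358) or without the filter on dim probes, though the differences stayed about as large. Without that filter 8 probes passed at 10 h, and without background subtraction 280. With chip position 4 of the 24 called genes followed singly at 10 h missed and 20 kept their call. KLF9 (adjusted p = 0.05907) and S100A11 (0.05595) were among those that missed. These fits were added after the data had been seen.

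**Figure D3:**
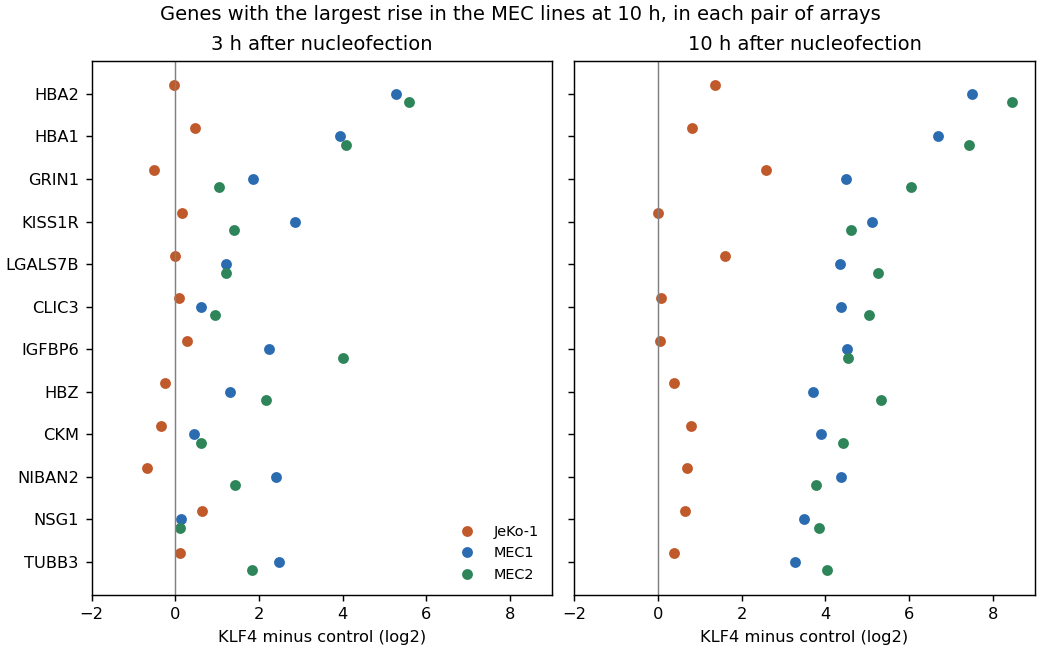
Log2 difference between the KLF4 array and its control in each line, at 3 h (left) and 10 h (right). The 12 genes have the largest rise in the MEC lines at 10 h among those that passed. The MEC1 and MEC2 points at 10 h lie right of those of JeKo-1 in every gene, with HBA2 at 7.50 in MEC1, 8.45 in MEC2 and 1.35 in JeKo-1.

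Over both times, the comparison takes the average of the plasmid effects at 3 h and 10 h. ANXA1 was higher in 6 of 6 pairs, by 1.87 on average. CXCL8 was lower in all 6 pairs, by -0.89 ± 0.13. CARD19 (0.87), the antiviral gene SAMD9 (0.79), SLC8B1, ATL1 and GRIN1 (2.59, mostly from 10 h and -0.50 in JeKo-1 at 3 h) were the other higher genes, and SPINK2, CLCN5, NADK2, SOS1 and HCN4 the other lower ones. Limma called 0 probes (smallest adjusted p = 0.4364), with 1669 at unadjusted p under 0.05. All 6 pairs moved alike in 4.5% of probes, against 3.12% by chance. Leaving out JeKo-1 gave 24 probes, while subtracting no background and using the deposited values gave 5 each and an intensity trend gave 4.

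Over both times, 6 lists passed with the preset correlation, each lost with an estimated correlation. Interferon-stimulated genes were higher (median 0.13, camera adjusted p = 0.004386, adjusted p = 0.7068 with an estimated correlation), which without JeKo-1 became a median of 0.01 (adjusted p = 0.8731) and without MEC1 0.21. NK cell markers were higher (0.64) and NF-kB and cytokine genes lower (-0.16), both with adjusted p = 0.004386 and adjusted p = 0.4403 with an estimated correlation. Without MEC1 the NF-kB list had a median of -0.08 (adjusted p = 0.222) and without MEC2 -0.25, and the NK markers had 0.31 and 0.30. Ribosome biogenesis was lower (-0.09, adjusted p = 0.03692, fry adjusted p = 0.04368) and heat shock higher (0.06, adjusted p = 0.04281), each with adjusted p = 0.4403 with an estimated correlation. The NOTCH pathway was higher (0.14, adjusted p = 0.04564, adjusted p = 0.5986 with an estimated correlation), with 3 members adjusted over the list alone. Leaving out any 1 line raised the ribosome list's adjusted p to 0.1748 (JeKo-1), 0.1846 (MEC1) or 0.1266 (MEC2), with medians of -0.10, -0.07 and -0.10. Heat shock reached 0.2892 without MEC1 (median 0.11) and 0.1546 without MEC2 (0.06), and NOTCH 0.504 (0.11) and 0.1311 (0.03). Without background subtraction the NOTCH median was 0.06 and the NK median 0.35. Median scaling ended some of these calls too, at 0.09054 for ribosome biogenesis and 0.05612 for both heat shock and NOTCH.

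The difference between the plasmid effect at 10 h and at 3 h asks which responses grow with time. The interferon-stimulated genes differed most, with a median of 0.45 and 21 of 21 members positive (camera adjusted p = 1.758e-06, adjusted p = 0.7089 with an estimated correlation, fry adjusted p = 0.523). Ribosome biogenesis was lower, with a median of -0.25 and 2 of 11 members positive (adjusted p = 0.01553, adjusted p = 0.6293 with an estimated correlation, fry adjusted p = 0.01821). Without JeKo-1 its median was -0.26 (adjusted p = 0.2126) and without MEC2 -0.27 (0.1513), so that the size stayed while the call ended. The interferon median was 0.25 without JeKo-1 and 0.71 without MEC2. Of single genes, CCDC88B, a T-cell and myeloid scaffold protein (1.35), CPLX1, HERC6, JUP and FAM163B had the smallest p among higher ones, and HEATR3, SINHCAF, CCR8, HNRNPCL1, ITGA11 and PTGR3 among lower ones. None passed: limma called 0 probes (smallest adjusted p = 0.7201), with 1362 at unadjusted p under 0.05.

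The difference between the MEC lines and JeKo-1 in the plasmid effect asks whether the lines respond alike. Among the genes with the smallest p or named from the lists, none of which passed, LFNG, which adds sugars to NOTCH receptors, differed by 1.86 ± 0.25, NRARP, a feedback inhibitor of NOTCH, by 1.29 ± 0.19, HES4 by 1.95 and HES5 by 1.35, all higher in the MEC lines. The neuronal receptor RTN4R (2.07), KLHL26, ATOSB and FBXO41 were the others higher, and the immune checkpoint CD200 (-1.20), FAHD2CP, ZNF736, ZNF512B, FAM86JP and H2BC7 were lower. As a list, the NOTCH pathway had a median of 0.32 (camera adjusted p = 0.0005979, adjusted p = 0.5117 with an estimated correlation, fry adjusted p = 0.06166), with 2 members adjusted over the list alone. Interferon-stimulated genes had a median of -0.44 (adjusted p = 4.015e-05, adjusted p = 0.6052 with an estimated correlation), with IFI44 at -0.80, IFIT2 at -0.97 and the chemokine CXCL10 at -0.64. Epithelial differentiation genes had a median of 0.46 (adjusted p = 0.01932, adjusted p = 0.6052 with an estimated correlation), with the tight junction gene CLDN4 at 1.15. The plasmid difference of CLDN4 at 3 h and 10 h was -0.09 and -1.71 in JeKo-1, -0.50 and 0.23 in MEC1, and 1.66 and -0.41 in MEC2. The 1.15 thus reflects the low JeKo-1 value at 10 h and no common rise in the MEC lines. Without MEC1 the epithelial list reached 0.1039. Without background subtraction its median was 0.20 and that of the NOTCH list 0.16. No gene passed: limma called 0 probes (smallest adjusted p = 0.7514), with 985 at unadjusted p under 0.05 where chance gives 1057. Without background subtraction 5 probes passed.

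Between 3 h and 10 h in the empty-vector arrays, the comparison asks what happens after nucleofection without KLF4. The immediate-early genes, transcription factors and phosphatases that answer a stimulus within minutes, fell: FOSB by -5.19 ± 0.29 (log2, SE, n = 3 lines, fold 36.6), FOS by -4.62 (fold 24.6), NR4A2 by -3.46, EGR3 by -3.33, EGR1 by -2.45, DUSP1 by -2.01 and JUN by -1.90. Other genes that fell were CXCL8 by -2.84, the early activation marker CD69 by -2.59, the chemokine CCL4L1 by -2.45, CD83 by -1.59 and the NF-kB inhibitors NFKBIA and TNFAIP3 by -1.14 and -1.13. RGCC (-2.35), RAB11FIP1 (-2.33) and TAGAP (-2.29) completed the largest falls. KLF2, which keeps lymphocytes quiescent, fell by -1.57 and its relative KLF6 by -1.60. Of 12 cholesterol synthesis genes 5 fell, while the call of the list was lost with an estimated correlation (adjusted p = 0.2111): HMGCS1, which makes the precursor HMG-CoA, by -2.18, the sterol sensor INSIG1 by -1.56, IDI1 by -1.22, FDPS by -1.03 and DHCR7 by -0.93. Under median scaling IDI1 (adjusted p = 0.05648) and DHCR7 (0.138) missed.

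Among the genes that rose between 3 h and 10 h were several that supply amino acids or charge transfer RNAs: SLC6A9, a glycine transporter, by 2.61 ± 0.27 (fold 6.10), PSAT1 by 1.79 and PHGDH by 1.49 (serine synthesis), the folate enzyme MTHFD1L by 1.64, the tryptophan synthetase WARS1 by 1.71 and ASNS (asparagine synthesis) by 1.49. INHBE, a stress-induced secreted factor, rose by 2.28, the lysosomal protein TM6SF1 by 2.12, the inositol kinase ITPKA by 2.11 and RPS6KA2 by 2.02 (at least 3.72-fold). IRF2 (1.60), ZNF425, NAV2 and ZNF485 were the other genes with the largest rise. The plasma cell factor PRDM1 rose by 1.43 and its opposite in B-cell identity, EBF1, by 0.95. Of the remaining list examples, AURKA (1.08), XPC (0.64) and DKC1 (0.60) rose and the chaperone DNAJA1 fell by 0.66. GNLY (1.24) passed too, but not without background subtraction (1.09, adjusted p = 0.06316), without the filter (0.06258) or with its probes averaged (0.96, 0.1011).

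In all, 1041 of 21141 probes passed with time, 667 higher and 374 lower, for 551 and 261 genes. At unadjusted p under 0.05 there were 4767. The count was 562 without JeKo-1, 10 without MEC1 and 8 without MEC2. Of 48 called genes that were followed singly, 4 passed whichever line was left out: FOSB, NR4A2, EGR3 and RAB11FIP1, with a highest adjusted p of 0.04744. Without MEC1 and without MEC2, FOS differed by -5.07 (adjusted p = 0.0961) and -4.88 (0.09241), HMGCS1 by -1.90 (0.1243) and -2.17 (0.1374), and SLC6A9 by 2.76 (0.1031) and 2.61 (0.09241), so these genes missed at a similar size. It was 28 with the empty-vector arrays alone and 105 with chip position as a covariate. The excess of higher probes was not kept in these fits: 277 were higher and 285 lower without JeKo-1, 1 and 9 without MEC1, 1 and 7 without MEC2, 3 and 25 with the empty-vector arrays alone, and 52 and 53 with chip position. The count was 1676 without background subtraction. Median scaling raised it to 1634, with 86.8% of called probes higher against 64.1%, and moved the median of all genes from 0.05 to 0.20. Without the replicate block, which pairs the arrays by line, 6 probes passed here and 18 in the MEC lines at 10 h. The plasmid comparisons of all 3 lines kept their 0 without the block, while their probes at unadjusted p under 0.05 dropped to 181 at 3 h, 283 at 10 h, 263 over both times and 184 for the difference between the times.

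Among the lists, immediate-early genes were lower with time (median -1.69, camera adjusted p = 1.169e-15, adjusted p = 0.002156 with an estimated correlation), and 11 of 19 fell, or 15 adjusted over the list alone. Cholesterol synthesis was lower (-0.91, adjusted p = 2.917e-08, adjusted p = 0.2111 with an estimated correlation, fry adjusted p = 0.007552), with all 12 members negative and 5 of them fallen, or 8 adjusted over the list alone. NF-kB and cytokine genes were lower (-0.33, adjusted p = 0.03022, adjusted p = 0.2111 with an estimated correlation), with 4 of 14 fallen; without MEC1 the median was -0.16 (adjusted p = 0.1192), without MEC2 -0.09 (0.0681) and without JeKo-1 -0.59. Fry alone also called heat shock (-0.27, fry adjusted p = 0.04937), housekeeping (-0.34, 0.04747), the KLF and SP family (-0.05, 0.02217) and B-cell identity (-0.08, 0.04937) lower and ribosome biogenesis higher (0.13, 0.02217). The list of unfolded protein and amino acid stress did not pass (median 0.09, camera adjusted p = 0.9075), with 1 of 13 members, ASNS, risen. The medians of the KLF and SP family and of B-cell identity turned to 0.07 and 0.03 under median scaling. Leaving out 1 line moved the medians called by fry alone. Heat shock had -0.16 without JeKo-1, -0.43 without MEC1 and -0.36 without MEC2, and housekeeping had -0.19, -0.46 and -0.41. In the same order B-cell identity had -0.22, -0.19 and -0.15, each larger in size than its -0.08 with all lines. Ribosome biogenesis had 0.11, 0.15 and 0.17. Only the KLF and SP family changed sign, at -0.19 without JeKo-1 and 0.04 without MEC2.

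**Figure D4:**
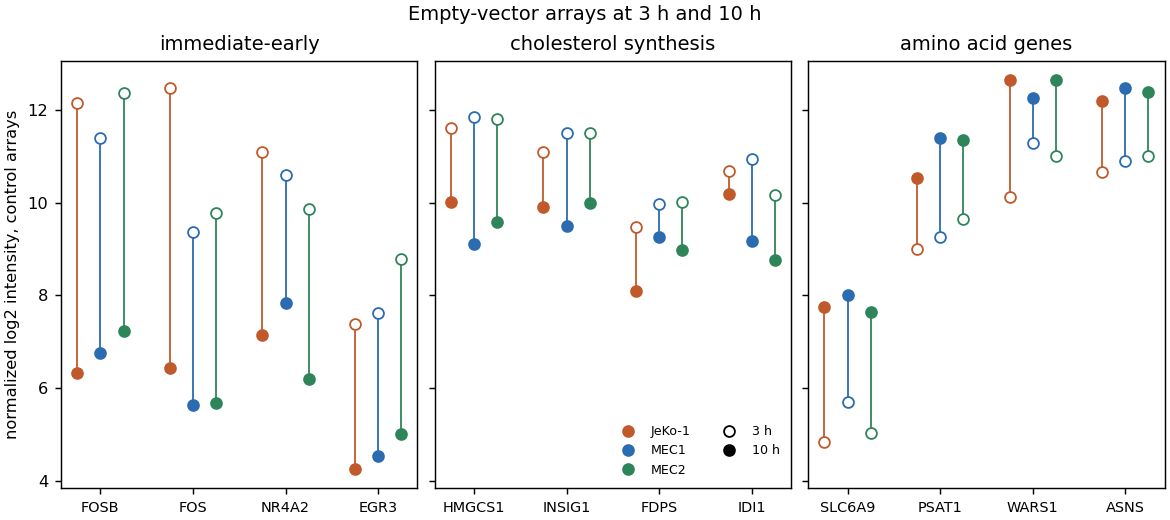
Normalized log2 intensity of immediate-early, cholesterol synthesis and amino acid genes in the empty-vector arrays of each line, with open circles for 3 h and filled circles for 10 h, joined by lines. The 4 immediate-early and 4 cholesterol genes are lower and the 4 amino acid genes higher at 10 h in every line.

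The comparison of the MEC lines with JeKo-1 asks how the leukemia and the lymphoma lines differ whatever the plasmid and time. The MEC lines had more of the antigen-presenting chain HLA-DRB5 (6.99, at least 122-fold), the homeobox factor LHX2 (6.70, at least 95.7-fold), CYP1B1 (6.44, at least 78.5-fold), the granule protein GNLY (6.37), the metal-binding MT2A (6.34) and the receptor SLAMF1 (6.23, at least 63.5-fold). JeKo-1 had more of IGLL1, the surrogate light chain of early B cells (-8.53 ± 0.14, detected on 2 of 8 MEC arrays), the ion channel TRPM4 (-7.63, at least 181-fold lower), the kinase co-activator TCL1B (-7.28), DPEP3 (-6.69, at least 85.8-fold lower), EEF1A2 (-6.45, and in MEC1 and MEC2 also 5.00 and 4.25 higher in the KLF4 array at 10 h), CD247 (-6.23) and the cancer-testis antigens CTAG2 (-6.44, at least 83.2-fold lower) and MAGEB2 (-6.18, at least 61.9-fold lower). SOX11, a marker of mantle cell lymphoma, differed by -5.23, TCL1A by -5.99 and ROR1 by -3.01 (at least 7.40-fold lower). CCND2 (5.86), FCER2 (5.01), the low-affinity IgE receptor of leukemic cells, and CD27 (2.85), of memory B cells, were higher in the MEC lines. CCND1, the cyclin that the mantle cell translocation drives, was higher in the MEC lines by 4.79. It was read by 1 probe, whose place on the transcript was not used here, and it was detected on 2 of the 4 JeKo-1 arrays.

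B-cell genes were split between the lines. The complement receptor CR2 (5.28, at least 36.3-fold), the inhibitory receptor CD22 (2.13) and MS4A1, which encodes CD20 (1.30), were higher in the MEC lines, and BACH2 (-3.93, at least 13.1-fold lower), the kinase SYK (-2.98), BCL6 (-2.04) and CD79B (-1.68) in JeKo-1. Of 21 B-cell identity genes, 7 were higher and 10 lower in the MEC lines, and the 12 leukemia and lymphoma markers split into 6 and 6. Of 21 interferon-stimulated genes, 12 were higher in the MEC lines and 0 lower, or 12 and 1 adjusted over the list alone, where CXCL10 was lower. The 3 NK cell markers were also higher. Of these PRF1 did not pass without MEC1 (adjusted p = 0.3251), and the interferon-stimulated HERC5 did not pass without MEC2 (0.09128). NF-kB and cytokine genes were 7 higher and 2 lower of 14, with CCL22 (4.61) and LTA (4.38) higher. The cell-cycle inhibitors CDKN1C (-3.76) and CDKN2A (-1.81), the death gene HRK (-4.28), the stress factor DDIT3 (-3.16) and MYC (-1.99) were lower in the MEC lines, while BAX (1.37) and NOTCH1 (2.22) were higher. In all, 9857 probes passed (46.6% of 21141), 4655 higher and 5202 lower, for 3133 and 3474 genes. With the empty-vector arrays alone the count was 5216. Medium and line cannot be told apart here.

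**Figure D5:**
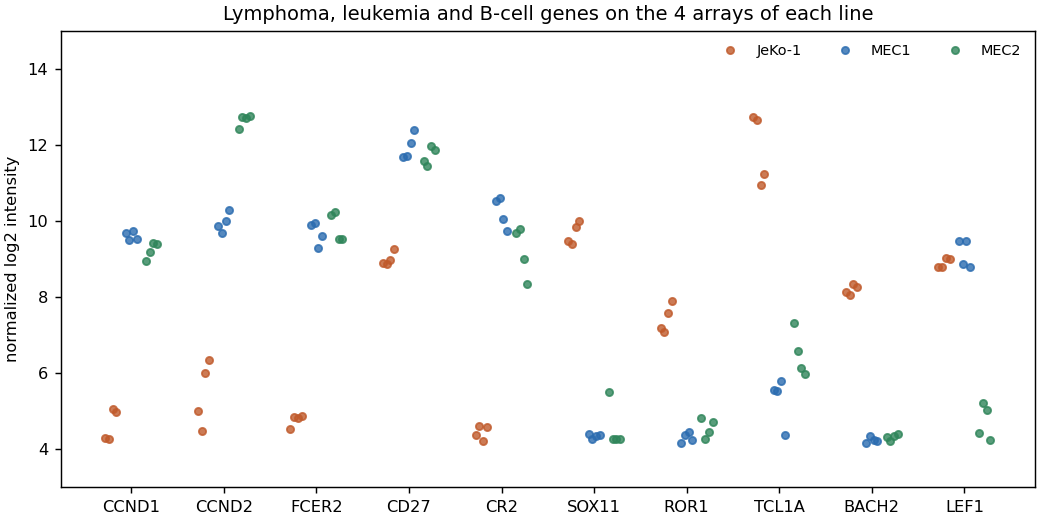
Normalized log2 intensity of leukemia, lymphoma and B-cell genes on the 4 arrays of each line (points, by line in colour). SOX11 and TCL1A are high in JeKo-1, CCND2 and FCER2 in the MEC lines, and LEF1 differs between MEC1 and MEC2.

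The sister lines MEC1 and MEC2, grown in 1 medium, also differed widely. MEC2 had more of GTSF1, which guards the germline against transposons (6.22, at least 70.4-fold), the matrix protein CCN3 (5.17, at least 31.6-fold), the protease inhibitor CST3 (4.78), PLS3 (4.57) and ST3GAL6 (4.42). The antiviral genes IFIT1 (4.27), IFIT2 (4.11) and OASL (3.60) were higher in MEC2, with 9 of 21 interferon-stimulated genes higher and 0 lower, or 15 adjusted over the list alone. Myeloid markers were higher too, 4 of 5, with S100A9 at 3.80. MEC1 had more of FAM174B (-6.00), CLECL1 (-5.91, at least 52.7-fold lower in MEC2), the collagen-modifying P3H2 (-5.69), the lysosomal transporter SLC15A4 (-5.50), PITX1 (-5.01), the B-cell regulator FOXO1 (-4.80, at least 26.2-fold lower) and LEF1 (-4.42), a WNT factor that marks chronic lymphocytic leukemia. DLGAP1-AS5 was also higher, and PRXL2C and MORF4L2 lower. HES4 (-2.63) and NOTCH1 (-1.51) were lower in MEC2, where 2 NOTCH genes were higher and 6 lower. CCND2 (2.69), CDKN2A (1.63), TNFRSF10A (1.64) and NKG7 (2.64) were higher, and PRF1 (-4.30) lower. Ribosome biogenesis genes were 5 higher and 1 lower of 11. In all, 5246 probes passed (24.8%), 2467 higher and 2779 lower, for 1613 and 2056 genes. With the 3 h arrays alone the count was 2922, and with the empty-vector arrays alone 1236, where IFIT2 (adjusted p = 0.05491) no longer passed.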

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

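The tests of the stress lists and of each line's interferon genes were chosen after the result was seen, and the splits of the arrays before. Each result here stands out because the plasmid effect differed between the times or between the MEC lines and JeKo-1 in a direct test of that difference.

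The list of interferon-stimulated genes had a larger plasmid difference at 10 h than at 3 h (median 0.45, camera adjusted p = 1.758e-06) and a smaller one in the MEC lines than in JeKo-1 (median -0.44, adjusted p = 4.015e-05), while none of its members passed. Both calls were lost when the correlation among these genes was estimated (0.7089 and 0.6052), and fry made neither (0.523 and 0.4638). Most of both came from the JeKo-1 pair at 10 h, where 21 of 21 members were higher with a median of 0.97, while the JeKo-1 pair at 3 h had a median of 0.02. Without JeKo-1 the difference between the times was smaller, with a median of 0.25 (adjusted p = 0.02832).

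Stress left over from nucleofection argues for more immediate-early, NF-kB and heat shock RNA in the same array. That was not found: 28.9% of the 45 members of these lists were higher in the JeKo-1 pair at 10 h, and their median was -0.07. These values cover only stress still present at 10 h. The immediate-early genes fell with time in the control arrays (median -1.69), so an earlier, unequal stress could have left no trace in them. Unequal sensing of the plasmid DNA by the JeKo-1 cells, with the interferon genes as its readout, could also give the 0.97. It stays open, because the labels give 1 such pair and no untransfected cells. A response of JeKo-1 to KLF4 itself stays open for the same reason and was not tested.

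NOTCH pathway genes differed toward the MEC lines (median 0.32, camera adjusted p = 0.0005979, 0.5117 with an estimated correlation), led by NRARP, HES4 and HES5, which answer the cleaved receptor. Epithelial differentiation genes differed the same way (median 0.46, adjusted p = 0.01932, 0.6052 with an estimated correlation). Without background subtraction the medians were smaller, at 0.16 for NOTCH and 0.20 for the epithelial genes. Ribosome biogenesis genes, which feed growth, were lower at 10 h relative to 3 h (median -0.25, adjusted p = 0.01553, 0.6293 with an estimated correlation). No explanation was tested for these lists.

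At the level of probes, the difference between the times gave 1362 probes at an unadjusted p under 0.05, and 2 of the 10 splits of the 6 pairs into 3 and 3 gave as many, the highest other giving 2208. For the difference between the MEC lines and JeKo-1, in a fit with 2 classes, 920 probes were below that p, and 10 of the 15 splits gave as many, the highest other giving 1634. In both designs the splits are too few for a share under 0.05.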

How the results depend on the processing

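The fits of the MEC lines alone and the list medians under each normalization were added after the data were seen, while the other alternatives were planned. The cause was not tested for any change given here, except where fewer arrays or probes show it.

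Without background subtraction limma called 46 probes for KLF4 at 10 h, 5 over both times, 5 for the MEC lines minus JeKo-1, 1676 for time, and in the MEC lines 9 at 3 h and 280 at 10 h. The deposited normalized values, which lack that step too, gave 55, 5, 4, 1710, 6 and 266. An intensity trend with robust variance gave 36 for KLF4 at 10 h, 4 over both times, 4 for the MEC lines minus JeKo-1, and 6 and 247 in the MEC lines. An offset of 50 gave 4 for KLF4 at 10 h and 194 in the MEC lines at 10 h. The 37 genes called in the MEC lines are dim, with a median control level of 5.02 against 7.40 for all genes. The 280 probes held all 54 of the MEC lines at 10 h.

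Median scaling gave 1634 probes with time. It moved the median of all genes to 0.204 with time, 0.153 in the MEC lines at 3 h and 0.113 for the MEC lines minus JeKo-1, and lowered the share of higher probes for MEC2 against MEC1 from 47.0% to 34.7%. Chip position as a covariate gave 105 with time and 0 in the MEC lines at 3 h. Without a filter, which tests more probes, 1 and 8 passed in the MEC lines. Dropping the replicate block gave 6 with time and 18 in the MEC lines at 10 h, and the line as an additive block gave 94. With fewer arrays, the empty-vector arrays gave 28 with time, 5216 for the MEC lines against JeKo-1 and 1236 for MEC2 against MEC1, and the 3 h arrays gave 2922 for MEC2 against MEC1.

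Leaving out 1 line gave 0 to 3 probes for KLF4 at 3 h, 0 to 54 at 10 h and 0 to 24 over both times, the highest each time without JeKo-1. For time it gave 8 to 562. In these fits a line left alone is assumed to vary like the others. A line could not be left out of a comparison that needs it, and the MEC fits leave no residual degrees of freedom without 1 line.

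Of the counts, 85 stayed within 1.5 times or on the same side, 24 were larger and 13 smaller. Of the single genes that were followed, 3156 values stayed on the same side of the threshold, whether passed or not, 82 gained a call, 262 lost it and 0 turned direction. That 0 does not cover every gene named here. TERT at 10 h, for example, differed by 0.57 in JeKo-1, -0.52 in MEC1 and -0.07 in MEC2. Of 48 called genes followed singly with time, 44 missed without at least 1 line. For lists, 12 outcomes, called or not, were the same with an estimated correlation or fry, 5 calls were gained and 31 lost. The 5 gained were lists called by fry alone. Their 5 missing calls with an estimated correlation count among the 12. Signal over background of 13.1 to 17.9 limits genes near the floor. Where a probe was detected on no array of a group the fold is a lower bound, and where it was detected on some the difference is measured partly against background.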

Other observations

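The tests of the globin genes, of JeKo-1 and of the amino acid genes were chosen after the result was seen, and the splits of the arrays before.

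Some annexins and S100 proteins, which bind calcium and pair at the cell membrane, had higher values with the KLF4 plasmid at 10 h. ANXA1 differed by 2.28 ± 0.32 and its relative ANXA2 by 0.73 ± 0.14 (log2, SE). S100A10, which partners ANXA2, differed by 2.47 ± 0.53, S100A11, which partners ANXA1, by 1.46, and the motility proteins S100A4 and S100A6 by 1.58 and 1.37. These 6 genes were higher in each line at 10 h. Of the 16 measured members 14 were above 0 with a median of 0.34, and others stayed near 0 or below: ANXA5, ANXA6 and ANXA7 were at 0.02, -0.06 and 0.00, and S100A14, S100A13 and S100A8 at 0.01, 0.13 and -0.24. The family was not tested as a set. None of the 16 passed over all probes, the adjusted p of the 6 running from 0.2891 to 0.3316, and the 6 were chosen after their values were seen. In the MEC lines alone S100A11 passed.

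The synthetases that charge transfer RNAs split with time in the empty-vector arrays. AARS1 rose by 1.36, SARS1 by 1.28, MARS1 by 1.13 and NARS1 by 1.05, while KARS1, QARS1 and FARSB stayed at -0.18, -0.16 and -0.05. The split was not clean: among the genes not known as ATF4 targets RARS1 rose by 0.57 and FARSA differed by 0.47, and the target VARS1 stayed at 0.05. Of 24 other genes of amino acid supply and the stress response to its lack, chosen after the data were seen, 10 rose and 0 fell. Among them were PHGDH by 1.49, PCK2 by 1.58 and SLC7A5 by 0.99, while PSPH, MTHFD2 and SLC7A11 missed at 0.1408, 0.05315 and 0.06136. These calls needed all 3 lines for several genes. PSAT1 missed without MEC1 (1.61, limma adjusted p = 0.0961) and without MEC2 (1.84, 0.09769). SLC6A9, MTHFD1L and INHBE also missed in both fits. A candidate explanation is a response of the ATF4 type, in which cells short of amino acids translate ATF4. The 12 synthetases known as its targets had a median of 0.90 and all 12 were higher, against 0.05 and 3 higher of the 6 others. The difference of means was 0.81 (exact permutation over genes, one-sided p = 0.0007003), though genes are not independent replicates. The RNA of ATF4 itself moved by 0.09, which leaves the hypothesis open since ATF4 is controlled in translation, while its targets DDIT3 and CHAC1 differed by -0.42 and -0.22. Of technical factors, chip position was fitted as a covariate. With it 27 of the 48 called genes followed singly with time missed and 21 kept their call. WARS1 (1.71, limma adjusted p = 0.09091) and INHBE (2.13, 0.1309) missed at a similar size. No other technical explanation was tested for these genes beyond the alternative processing.

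Alpha-globin genes were the most raised with KLF4 in the MEC lines. At 10 h the alpha cluster had a median of 4.52 over 5 genes, with HBA2 at 7.97, the beta cluster 0.05 over 5 genes, and 11 other erythroid genes -0.10. The values argue against adult erythroid cells in the samples, since these would bring HBB, which differed by 0.11 and was detected on no KLF4 array. The beta-cluster genes HBE1, HBG1 and HBG2 differed by -0.04, 0.05 and -0.23. No probe of the beta cluster was detected on any array, so the data do not show that these probes can read their genes. Erythroid cells are therefore not excluded. Probes binding plasmid sequence would rise in every line, and HBA2 in JeKo-1 differed by -0.03 at 3 h, when MEC1 and MEC2 had 5.28 and 5.58, and by 1.35 at 10 h. How much plasmid JeKo-1 took up was not measured, so this stays open. A response of the whole alpha cluster also stays open: HBM and HBQ1, of the same cluster, differed by 0.54 on average. HBM differed by 1.66 in MEC2 and 0.11 in MEC1, and HBQ1 was detected on no array.

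The 37 genes called in the MEC lines at 10 h had a median of 0.40 in JeKo-1. They were chosen for their size in the MEC arrays, which by itself makes a smaller value in another line probable. The direct test of the MEC lines against JeKo-1, over both times, called 0 probes in limma (smallest adjusted p = 0.7514, 985 at an unadjusted p under 0.05). It takes the 3 h and 10 h pairs of a line as replicates, so an effect that grows with time widens its spread. The 0 therefore does not show that the lines responded alike at 10 h. Without background subtraction this test called 5 probes. A compressed signal of bright probes on the JeKo-1 KLF4 array at 10 h was not seen. Its 95th percentile was 17.9 times the background, the highest of the 12 arrays. That ratio does not describe dim probes, and these genes were dim, with a median MEC control level of 5.02 against 7.40 for all genes. Compression near the floor therefore stays open. A lower uptake of plasmid with an equal response would scale all genes by 1 fraction of the increment. The median fraction was 3.7%, and 13.5% of the genes, 5 of 37, lay over 3 standard errors from it, all 5 below. The smaller median may reflect that choice of genes, lower uptake, a different response of JeKo-1, its other medium or compression near the floor. These cannot be told apart, since uptake was not measured and the median itself carries error.

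Other splits of the arrays were fitted for each count. The arrays grouped by line. MEC2 against MEC1 gave 5246 probes, and 1 of the 35 splits of the 8 MEC arrays, the real one, gave as many. The highest other gave 253. The MEC lines against JeKo-1 gave 7295 in a fit with 2 classes. Of 100 drawn splits 1, the real one, gave as many, the highest other giving 570. Splits that mix the lines put the line difference into the spread. These splits therefore show that the arrays of a line resemble each other, and cannot test a difference of lines against chance. For KLF4 over both times chance is not excluded: 4 of the 32 splits that part all 6 pairs gave as many as 1669 probes at an unadjusted p under 0.05, the highest other giving 1942. The 10 splits are too few for a share under 0.05 at 3 h, where the real count was 1198 and the highest other 1860, with 7 as large. They are also too few at 10 h (1860 and 1534, with 1 as large) and for time, where 1041 probes passed in the real split and 0 in every other.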
